A study of Mus musculus with 4 samples.

How the data were processed

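RNA was measured in 4 samples of mouse morulae, 2 injected with non-targeting siRNA (siNT) and 2 with an siRNA pool against Nr1h2 (siNr1h2). Per the labels' protocols, fertilized eggs were injected with 4 to 5 pL of 100 µM siRNA, cultured to the morula stage in M16 medium and used for full-length cDNA by template switching from polyadenylated RNA (SMART-Seq v4) and tagmentation libraries (Nextera XT). This kit does not mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart, which concerns Xist and Tsix. Per the submitters' processing notes, the tools were STAR, HTSeq 0.12.4, RSEM, Cufflinks 2.2.1, edgeR and DESeq2 and the genome build was mm9, with no role, order or parameters given. The gene annotation and the treatment of reads that match several copies of a gene are not given in the sources used here.

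The data analysed are 1 table of the authors' own comparison of siNr1h2 with siNT, with the column names of a DESeq2 results table, per the file headers. For each of 13658 genes it gives the authors' mean normalized count over all samples (a signal value, counts divided by size factors), the deposited log2 fold change with its standard error, the deposited Wald statistic (a score), and the deposited p-value and adjusted p-value. The direction, siNr1h2 over siNT, is that of the deposited comparison's name. The table holds no value per sample, so the total count of each sample is unknown, no test per gene was run again, and 0 columns of per-sample values were left out. The deposited statistic equalled the fold change over its standard error, so fold changes were not shrunken, and the deposited p-value equalled the two-sided p of the normal distribution. The adjusted p-value of the authors equalled the Benjamini-Hochberg value over 12069 genes. The other 1589 had mean normalized counts up to 8.00 and no adjusted p. Mean counts set the precision of the deposited values. The median standard error was 0.61 for genes with means of 8 to 50 and 0.13 for those above 1000, so that a gene of median precision needed a change of 4.02 and 1.35 times to be called.

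From these values, genes with an adjusted p under 0.05 were counted, folds were computed as powers of 2 with 95% intervals of 1.96 standard errors, and the share of higher genes was tested with an exact binomial test. The text names, by a rule set before the data were examined, the receptor genes, the 10 largest changes and 5 smallest adjusted p-values per direction among called genes with a mean normalized count of at least 50 and an assigned symbol, and up to 4 members with the smallest p-values per list, from which the text gives examples. The value of 1 gene that the rule names is not reported here. There were 25 gene lists, also set before the data were examined: nuclear receptor partners; LXR target genes; cholesterol synthesis and uptake; fatty acid oxidation and lipid storage; pluripotency and inner cell mass; trophectoderm; primitive endoderm; 2-cell and genome activation; maternal and oocyte transcripts; compaction, polarity and Hippo; p53 response; integrated stress and unfolded protein response; interferon response; glycolysis; cell cycle; chromatin and DNA methylation regulators; cumulus and granulosa cells; sperm; blood and immune cells; sex-linked; ribosomal proteins; oxidative phosphorylation; mitochondrial genome; histone genes; and retrotransposon rows. The 21 lists with at least 5 members in the table were tested with cameraPR of limma 3.58.1 (R 4.3.3) on the Wald statistic, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. An estimated correlation needs values per sample and could not be had, so a correlation of 0.05 was the alternative. Changed members were tested against all other genes with an adjusted p by Fisher's exact test, two-sided, adjusted over lists. Other steps used Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and scikit-learn 1.9.0.

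Chromosome, transcript length, GC content and 3′ untranslated sequence came from the GENCODE annotation of a later mouse build (GRCm38), by symbol for 99.3% of genes. No coordinates are given, because that build is not the one in the submitters' notes. The scripts were tested on simulated fold changes with the real standard errors of the 12069 genes of this comparison. Of 100 genes changed by 1 on the log2 scale 57% were recovered and of 100 changed by 2, 89%, with 6.41% false calls, and the list test found the 1 shifted list among 21. The simulated noise was normal, independent between genes and, for the calls, took the standard errors as exact. The simulation therefore checks the scripts and says nothing about errors in the standard errors or correlation between genes. Alternatives covered the threshold, a minimum fold, the low-count filter, Holm adjustment, centring, a t distribution, unnamed models, the statistic, the correlation and the background of the list tests. Leaving out replicates, a second count tool and a replicate block were planned for values per sample and were not run.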

Results

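The series profiled polyadenylated RNA of mouse morulae, the compacted embryos that precede the blastocyst, after an RNA interference treatment at the 1-cell stage. Fertilized eggs received 4 to 5 pL of small interfering RNA at 100 µM. It was directed either against Nr1h2, which encodes the oxysterol-activated nuclear receptor LXRβ, or against no mouse transcript (siNT, the non-targeting control). There were 4 samples, 2 per group, and the labels do not say how many embryos a sample held or whether the replicates were separate injection sessions. The p-values therefore measure the spread between these samples, part of which may be technical. The data consist of 1 comparison computed by the authors over 13658 genes, with no values per sample, so the sequencing depth of each sample is unknown from it. The mean normalized count per gene ran from 1.01 to 147367 with a median of 142 in the authors' deposited table.

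The comparison asks which transcripts depend on Nr1h2 before the blastocyst forms. The targeted transcript itself was 5.03 times lower in siNr1h2 than in siNT morulae in the authors' deposited table (95% interval 3.89 to 6.50, adjusted p = 3.61e-31). This leaves 19.9% of the control level (95% interval 15.4% to 25.7%), at a log2 fold change of -2.33 with a standard error of 0.19. Its paralogue Nr1h3 (LXRα) and the retinoid X receptors with which both form dimers did not pass the test. Their log2 fold changes in the authors' deposited table were -0.17 ± 0.75 (SE) for Nr1h3, 0.24 ± 0.19 for Rxra and 0.56 ± 0.23 for Rxrb. Adjusted over the list alone, Nr1h2 was lower and Rxrb higher (adjusted p = 0.0323, against 0.214 over all genes). The list holds the siRNA target itself, whose small p lowers the adjusted p of Rxrb, so that call rests in part on Nr1h2. Rxrg had a mean normalized count of 2.72 and no adjusted p in the authors' deposited table. The list of these 5 receptor genes gave a shift downward (cameraPR, adjusted p = 0.00613) that rested on Nr1h2, since the other 4 genes alone gave p = 0.375, upward, at the preset correlation of 0.01.

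At an adjusted p of 0.05 the authors' deposited table held 239 changed genes among the 12069 with an adjusted p, 184 lower and 55 higher in siNr1h2. The share of higher genes was 23.0% (exact two-sided binomial test against equal shares, p = 1.92e-17; genes are not independent, so the p describes the imbalance). The split depended on the scaling, since centring on genes with a mean normalized count of at least 500 gave 142 lower and 82 higher genes and centring on ribosomal protein genes 448 and 36, alternatives chosen after the data were seen. The median log2 fold change of all genes was 0.01 in the authors' deposited table, a value that division by size factors places near 0. A change of at least 2 times was seen for 66 of the lower and 24 of the higher genes. With p-values taken from a t distribution with 2 degrees of freedom, the number that 4 samples in 2 groups leave, 0 genes passed (smallest adjusted p = 0.948) and 68 had an unadjusted p under 0.05. With so few degrees of freedom the threshold over 12069 genes was out of reach even for Nr1h2, so this count says nothing about the stability of the calls. Removing a trend with transcript length and GC content, an alternative chosen after the data were seen, left 118 lower and 52 higher genes.

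**Figure D1:**
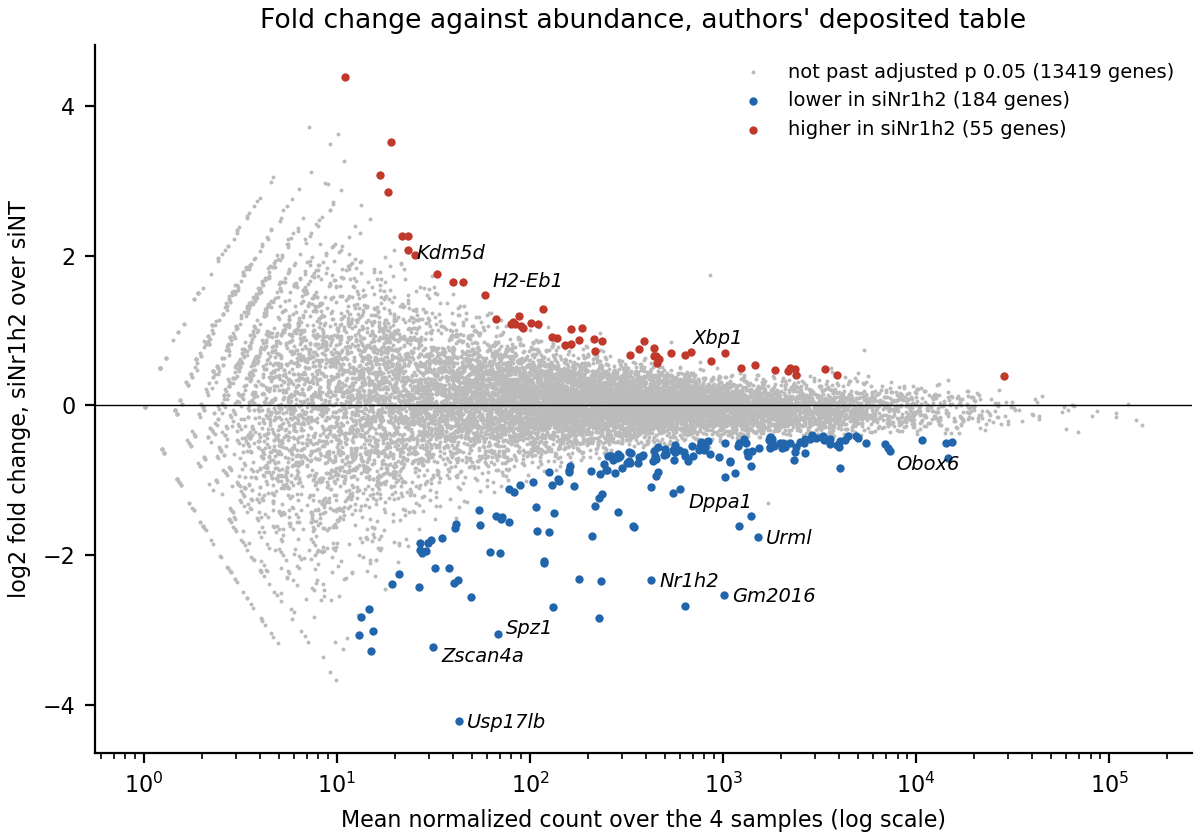
Each point is 1 of the 13658 genes in the authors' deposited table, with its mean normalized count over the 4 samples on a log axis and its log2 fold change, siNr1h2 over siNT. The 184 genes lower in siNr1h2 are blue, the 55 higher genes are red, and Nr1h2 sits at a log2 fold change of -2.33.

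Among lower genes with an assigned symbol and a mean normalized count of at least 50, the steepest change was that of Spz1, a basic helix-loop-helix transcription factor gene of the male germ line. It was 8.33 times lower in the authors' deposited table (95% interval 4.81 to 14.4), followed by Rgcc, a regulator of the cell cycle, at 7.16 times (5.13 to 9.99). The olfactory receptor gene Olfr376, the PRAME family gene Pramef25 and the zinc finger gene Zfp352 followed with log2 fold changes of -2.69 ± 0.29 (SE), -2.35 ± 0.23 and -2.08 ± 0.29 in the authors' deposited table. The mRNA export factor gene Nxf2 (-1.95 ± 0.40), Urml (-1.76 ± 0.15), BB287469 (-1.69 ± 0.29) and the Rac exchange factor gene Prex2 (-1.67 ± 0.29) complete, with Nr1h2, the 10 largest decreases among these genes in the authors' deposited table. Trim43c, of the tripartite motif family, was among the 5 with the smallest adjusted p (-1.61 ± 0.14, adjusted p = 5.81e-29, authors' deposited table). The 2 smallest p-values of all belonged to the gene models Gm2016 (-2.53 ± 0.17) and Gm8016 (-2.68 ± 0.20) in the authors' deposited table, which fall outside the naming rule and were picked after their values were seen. Unnamed models of this kind made up 21 of the 184 lower and 1 of the 55 higher genes.

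The largest increases among called genes with an assigned symbol and a mean normalized count of at least 50 were those of H2-Eb1, a class II histocompatibility chain (2.79 times, 95% interval 1.67 to 4.66), and Lrch4 (2.44 times, 1.67 to 3.57) in the authors' deposited table. Masp2, a protease of the complement lectin pathway, Capn6, Selenom, Ssbp4, the anchoring-fibril collagen gene Col7a1, the meiotic cohesin gene Stag3, the sphingosine 1-phosphate receptor gene S1pr5 and Mri1 had log2 fold changes between 1.04 and 1.20 in the authors' deposited table. Pdia6, an endoplasmic reticulum disulfide isomerase, had the smallest adjusted p among higher genes (0.72 ± 0.15, adjusted p = 0.000352, authors' deposited table). Tex19.2, the unfolded protein response factor Xbp1 and the small nucleolar RNA host gene Snhg20 followed Lrch4 with log2 fold changes of 0.77 ± 0.17, 0.67 ± 0.15 and 0.86 ± 0.20 in the authors' deposited table.

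**Figure D2:**
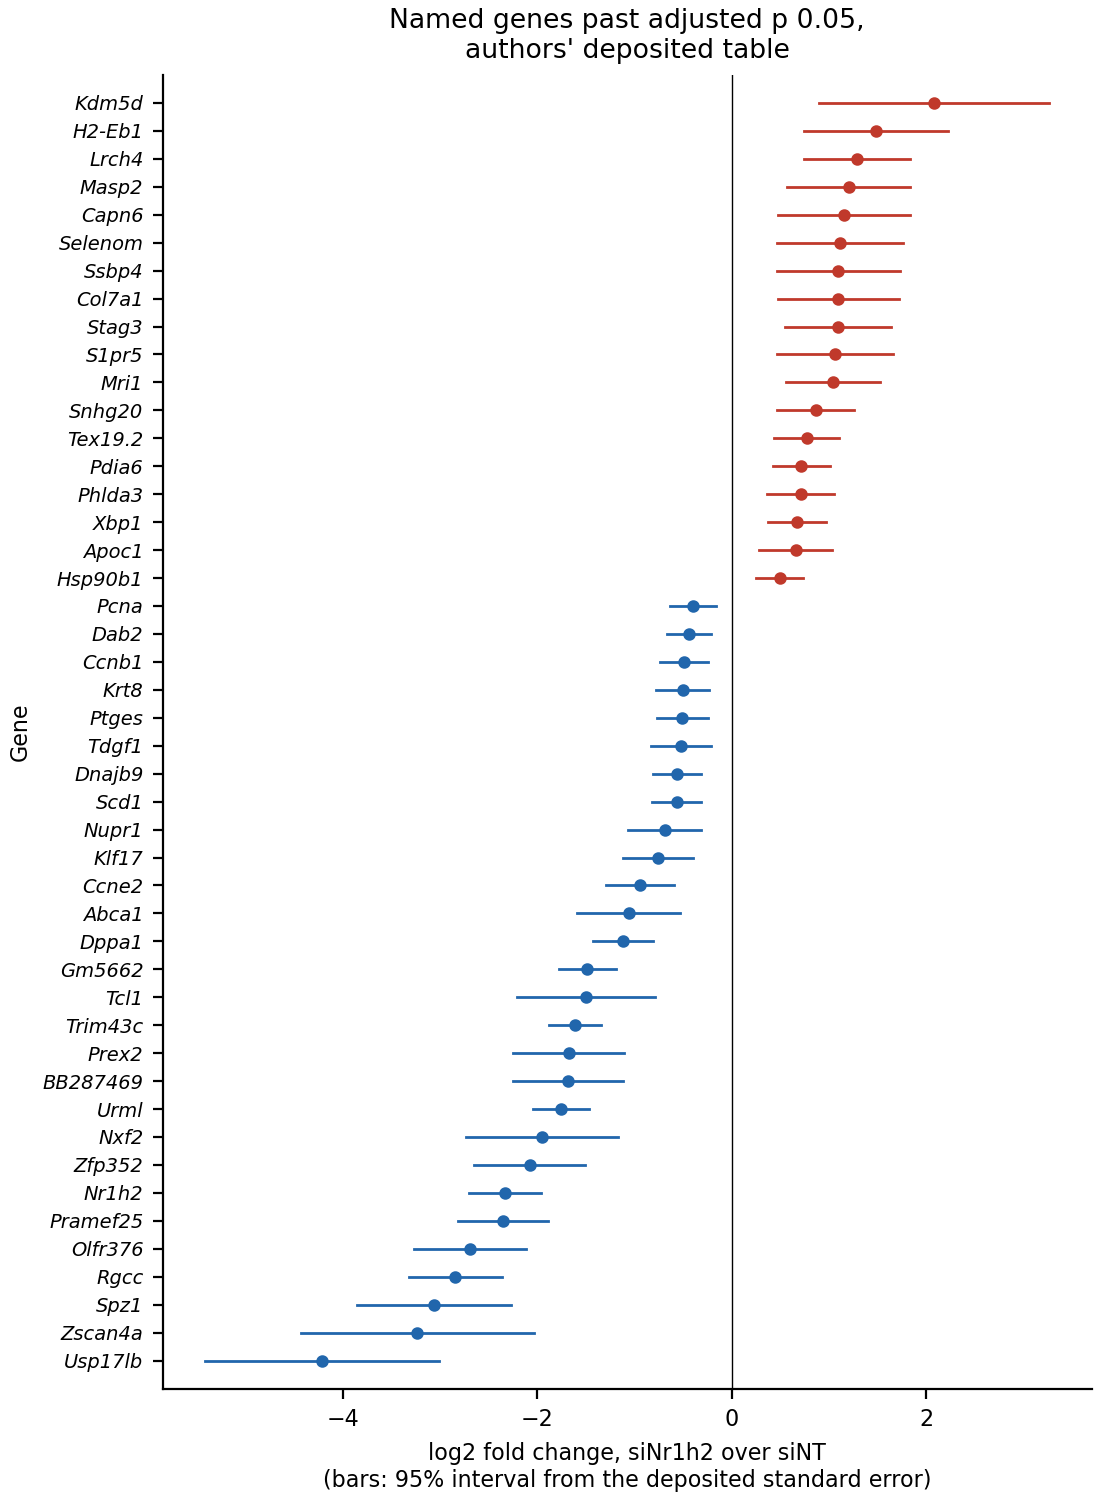
Log2 fold change, siNr1h2 over siNT, of the 46 named genes past an adjusted p of 0.05 in the authors' deposited table, with bars for the 95% interval from the deposited standard error. Decreases (blue) reach -4.21 for Usp17lb and increases (red) reach 2.08 for Kdm5d.

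Genes of the 2-cell stage and of genome activation formed the list with the smallest adjusted p in the cameraPR test on Wald statistics. Of 23 members in the authors' deposited table, 7 were lower and 0 higher, 14 did not pass and 2 had no adjusted p; adjusted over the list alone, 13 were lower and 1 was higher. Usp17lb, of a multi-copy deubiquitinase family, was 18.5 times lower in the authors' deposited table (95% interval 8.08 to 42.6), at a mean normalized count of 42.8. Zscan4a, of the zinc finger family that marks 2-cell-like cells, was 9.40 times lower (4.10 to 21.6) at a mean normalized count of 31.4. Its relatives Zscan4c (log2 fold change -0.96, adjusted p = 0.299, mean 41.8) and Zscan4d (0.04, adjusted p = 0.985, mean 36.8) did not pass. Zscan4b had no adjusted p. Adjusted over the list alone, Zscan4c was lower (adjusted p = 0.0452) and Zscan4d was not. Zfp352 was 4.22 times (2.84 to 6.28) and Gm5662 2.80 times (2.28 to 3.43) lower in the authors' deposited table. Obox6, the most abundant called member with a mean normalized count of 7170, was 1.48 times lower (1.23 to 1.77) in the authors' deposited table. The median log2 fold change of the list was -0.69 (cameraPR, Benjamini-Hochberg adjusted p = 1.81e-11), and changed genes were over-represented in it (Fisher's exact test, two-sided, adjusted p = 1.91e-06). On ranks of the Wald statistic cameraPR gave an adjusted p of 0.0122, the same as for the cell cycle and sex-linked lists. The values of single Usp17l, Zscan4, Tdpoz and Obox genes, and of Gm2022, Gm5662 and Gm8300, are uncertain, because near-identical copies can share reads.

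Targets of the liver X receptors were changed more often than other genes but not in 1 direction. Of 23 members in the authors' deposited table, Scd1, the desaturase of fatty acid synthesis (1.48 times lower, 95% interval 1.24 to 1.76), and Abca1, the sterol efflux transporter (2.08 times lower, 1.44 to 3.01), were lower. Apoc1, an apolipoprotein gene, was 1.57 times higher in the authors' deposited table (1.21 to 2.05), 18 members did not pass and 2 had no adjusted p. Srebf1, the lipogenic transcription factor, had a log2 fold change of -0.68 ± 0.24 in the authors' deposited table (adjusted p = 0.115). Adjusted over the list alone, 4 were lower and 2 higher. Fisher's exact test gave an adjusted p of 0.0372, which rose to 0.0961 and 0.114 when genes were called at 0.01 and 0.1. The list as a whole was not shifted past the threshold (cameraPR, adjusted p = 0.672), and its median log2 fold change of 0.01 differed in sign from its mean Wald statistic of -0.16. None of the 25 genes of cholesterol synthesis and uptake passed, over all genes or adjusted over the list alone, with Msmo1 at a log2 fold change of 0.34 ± 0.13 and Hsd17b7 at -0.43 ± 0.21 in the authors' deposited table (list adjusted p = 0.467). None of the 21 genes of fatty acid oxidation and lipid storage passed either, over all genes or adjusted over the list alone, although 15 lay above 0 (list adjusted p = 0.0344, upward; adjusted p = 0.143 at a correlation of 0.05). Acaa2 (0.37 ± 0.16), Plin3 (0.34 ± 0.15) and Hadha (0.45 ± 0.19) had log2 fold changes above 0 and Fabp3 (-0.24 ± 0.11) below 0 in the authors' deposited table.

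**Figure D3:**
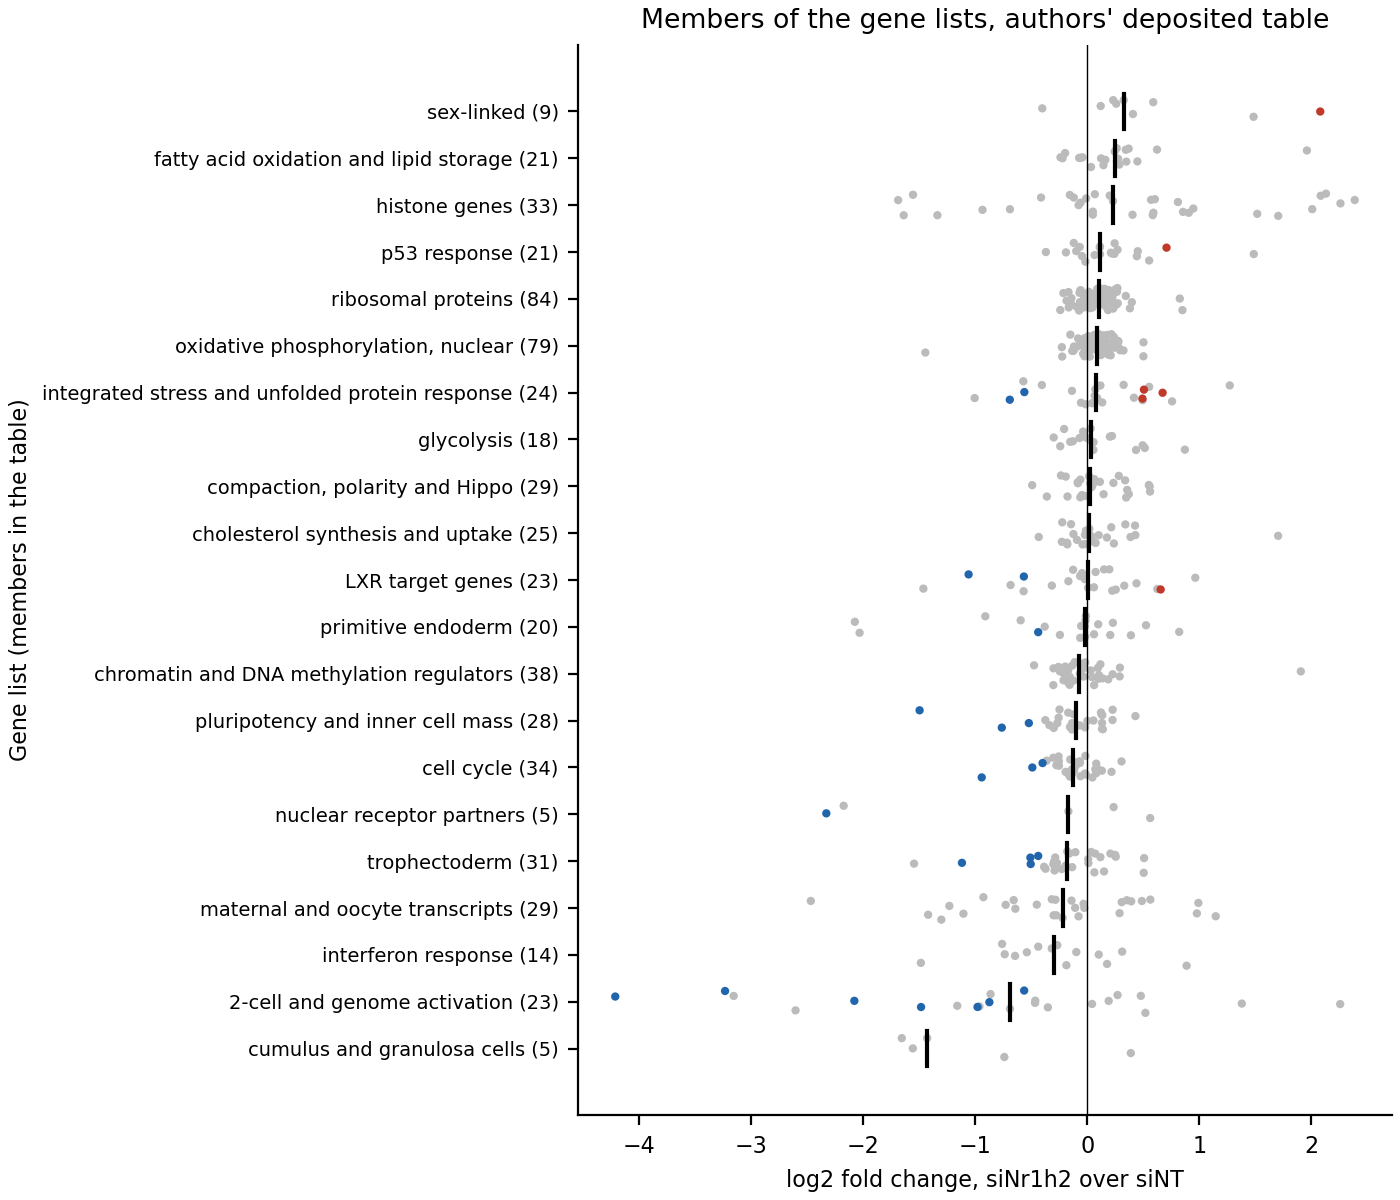
Log2 fold change, siNr1h2 over siNT, of each member of the gene lists with at least 5 members in the authors' deposited table; black bars are list medians, and colours mark members past an adjusted p of 0.05 (blue lower, red higher). The median of the 2-cell list lies at -0.69, and that of 5 cumulus and granulosa cell genes, of which none passed, at -1.43.

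Most genes of the lineage lists did not pass. In the trophectoderm list changed genes were still more frequent than among other genes at a threshold of 0.05. The pluripotency list missed that (Fisher's exact test, adjusted p = 0.0663). Over all genes, 239 of 12069 were called. Of 28 pluripotency and inner cell mass genes in the authors' deposited table, 3 were lower and 25 did not pass (adjusted over the list alone, 5 lower and 1 higher). The lower genes were Klf17 (1.70 times, 95% interval 1.32 to 2.18), Tcl1 (2.82 times, 1.72 to 4.62) and Tdgf1, a Nodal co-receptor (1.44 times, 1.16 to 1.78), in the authors' deposited table. Pramel7 had a log2 fold change of -0.34 ± 0.11 (adjusted p = 0.0957) in the authors' deposited table. The list was shifted downward, with 17 members below 0 and 11 above (cameraPR, adjusted p = 0.0285). Its adjusted p was 0.143 at a correlation of 0.05, 0.0737 on ranks and 0.375 on log2 fold changes. Core factors did not fall with it. Pou5f1, the 1 gene higher over the list alone, stood at 0.43 (adjusted p = 0.117 over all genes). Nanog stood at 0.06 and Sox2 at 0.23 in the authors' deposited table, and neither passed. Of 31 trophectoderm genes in the authors' deposited table, 4 were lower, 25 did not pass and 2 had no adjusted p (adjusted over the list alone, 4 lower and 1 higher). Dppa1, a pluripotency-associated gene that was put in this list, was 2.17 times lower (1.76 to 2.69), and the prostaglandin synthase gene Ptges, the endocytic adaptor gene Dab2 and the keratin gene Krt8 had log2 fold changes of -0.51 ± 0.13, -0.44 ± 0.12 and -0.50 ± 0.14 in the authors' deposited table. The trophectoderm list was shifted downward (cameraPR, adjusted p = 0.0110; adjusted p = 0.125 at a correlation of 0.05; p = 0.0270 without Dppa1). Fisher's exact test gave it an adjusted p of 0.0153, which rose to 0.721 and 0.0667 with calls at 0.01 and 0.1. Of 20 primitive endoderm genes only Dab2, shared with the trophectoderm list, passed in the authors' deposited table, also adjusted over the list alone, with Lamb1 at 0.39 ± 0.18 and Lamc1 at -0.38 ± 0.22 (list adjusted p = 0.453). None of 29 maternal and oocyte transcripts passed in the authors' deposited table, where Sohlh2 stood at 1.15 ± 0.35 (adjusted p = 0.0516; 1 higher adjusted over the list alone) and Dazl at -0.93 ± 0.32 (list adjusted p = 0.453). None of 29 genes of compaction, polarity and the Hippo pathway passed in the authors' deposited table, with 2 higher and 1 lower adjusted over the list alone. The polarity gene Pard3 stood at 0.56 ± 0.18, Ezr at 0.55 ± 0.19 and Amotl2 at -0.49 ± 0.17 in the authors' deposited table (list adjusted p = 0.229).

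Cell cycle genes shifted downward as a list (cameraPR, adjusted p = 0.00584; adjusted p = 0.0859 at a correlation of 0.05), with 26 of 34 members below 0. Of the 34, 31 did not pass in the authors' deposited table and 3 were lower, also adjusted over the list alone. They were Ccne2, the cyclin of S-phase entry (1.92 times lower, 95% interval 1.51 to 2.45), Ccnb1, a mitotic cyclin (1.40 times, 1.18 to 1.67), and Pcna, the replication clamp (1.32 times, 1.12 to 1.55), in the authors' deposited table. Gmnn had a log2 fold change of -0.30 ± 0.12 in the authors' deposited table (adjusted p = 0.173). None of 38 chromatin and DNA methylation regulators passed, over all genes or adjusted over the list alone, with Kdm6a at -0.30 ± 0.15 and Kdm4c at -0.48 ± 0.24 in the authors' deposited table (list adjusted p = 0.263). None of 33 genes matched as histones passed, over all genes or adjusted over the list alone (list adjusted p = 0.178), and 16 had no adjusted p. Their lowest p belonged to H13, a peptidase gene caught by the symbol pattern and not a histone, at 0.40 ± 0.15 in the authors' deposited table.

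Genes of the integrated stress and unfolded protein responses changed in both directions and more often than other genes (Fisher's exact test, adjusted p = 0.000697). Of 24 members in the authors' deposited table, 3 were higher and 2 lower, 18 did not pass and 1 had no adjusted p; adjusted over the list alone, 5 were higher and 2 lower. Xbp1 (log2 fold change 0.67 ± 0.15) and the endoplasmic reticulum chaperone genes Hsp90b1 (1.41 times, 95% interval 1.19 to 1.66) and Calr (1.42 times, 1.16 to 1.74) were higher in the authors' deposited table. The co-chaperone gene Dnajb9 (1.48 times lower, 1.24 to 1.75) and the stress-responsive gene Nupr1 (1.61 times lower, 1.24 to 2.10) were lower in the authors' deposited table. The list test gave a small upward shift (adjusted p = 0.0422; adjusted p = 0.195 at a correlation of 0.05). Of 21 p53 response genes only Phlda3, a p53-induced repressor of Akt signalling, passed in the authors' deposited table, 1.63 times higher (1.29 to 2.07), and Bbc3 (PUMA) stood at a log2 fold change of 1.49 ± 0.48 (adjusted p = 0.0701). Adjusted over the list alone these 2 were higher, and the list shifted upward (adjusted p = 0.0303; adjusted p = 0.143 at a correlation of 0.05). None of 14 interferon response genes passed, over all genes or adjusted over the list alone, with Ifi35 at -0.44 ± 0.24 and Bst2 at 0.31 ± 0.21 in the authors' deposited table (list adjusted p = 0.325).

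No gene of the ribosomal protein, oxidative phosphorylation or glycolysis lists passed the test. Of 84 ribosomal protein genes 60 lay above 0, with a median log2 fold change of 0.11 (list adjusted p = 0.0388, upward), and of 79 nuclear genes of oxidative phosphorylation 56 lay above 0, with a median of 0.08 (list adjusted p = 0.0422, upward). At a correlation of 0.05 both lists gave an adjusted p of 0.313, and neither had a member past the threshold adjusted over the list alone. Centred on the ribosomal protein genes, the median of the oxidative phosphorylation list was -0.02. Rps12 stood at 0.40 ± 0.16 and Ndufa6 at 0.29 ± 0.14 in the authors' deposited table. None of 18 glycolysis genes passed in the authors' deposited table, where the glucose transporter gene Slc2a1 stood at 0.51 ± 0.16 (adjusted p = 0.0614; 1 higher adjusted over the list alone; list adjusted p = 0.486).

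The sex-linked list held Y-linked genes and, of the X-linked genes, only Xist and Tsix. This list was shifted upward in siNr1h2 (cameraPR, adjusted p = 0.00584). X-linked genes as a whole went the other way, with 19 called lower and 1 called higher. Without Kdm5d the sex-linked list gave p = 0.00759 at the preset correlation of 0.01 (adjusted p = 0.0228 over the 3 lists tested without 1 gene) and p = 0.0175 at a correlation of 0.05 (adjusted p = 0.0524). Of 9 members in the authors' deposited table, 8 lay above 0, and the Y-linked demethylase gene Kdm5d was higher by 4.23 times (95% interval 1.86 to 9.61) at a mean normalized count of 23.4, also adjusted over the list alone. The other 8 did not pass, with Ddx3y at 0.33 ± 0.17, Zfy1 at 1.48 ± 0.84, Tsix at 0.41 ± 0.17 and Xist, the X-inactivation transcript, at 0.12 ± 0.14 in the authors' deposited table. Tsix overlaps Xist on the opposite strand, and reads of both are not separated without strand, so their values are uncertain. Without X- and Y-linked genes, an alternative chosen after the data were seen, 152 genes were lower and 48 higher, and the stress and oxidative phosphorylation lists no longer passed, at adjusted p of 0.0537 and 0.0577. Few listed markers of other cells were present: 5 of 17 for cumulus and granulosa cells, 1 of 11 for sperm and 3 of 15 for blood and immune cells. Mean normalized counts reached 542 for Serpine2 and 328 for Cd74 in the authors' deposited table, so RNA of other cells is not excluded. Of 5 cumulus and granulosa cell genes none passed, with Serpine2 at 0.39 ± 0.16 and Kitl at -1.66 ± 0.79 in the authors' deposited table (list adjusted p = 0.453). The test of that list on log2 fold changes in place of Wald statistics gave an adjusted p of 0.00207, and it also brought the histone list to 0.0193. The sperm list had 1 member, Ldhc, at 1.33 ± 0.81 in the authors' deposited table. The blood and immune list had 3, with Cd74, the class II invariant chain, at 0.42 ± 0.19 and Cd52 and Hba-a1 at -0.64 ± 0.63 and -0.18 ± 0.57 in the authors' deposited table. Both had under 5 members and were not tested, and none of these genes passed over all genes or adjusted over the list alone. The lists of mitochondrial genome genes and of retrotransposons matched 0 entries in the table.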

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

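The removal of a trend with length and GC content, the restriction to autosomes, centring on ribosomal protein genes or on means of at least 500 for the calls, and the use of 1 gene per 2-cell family were chosen after the data were seen. No paired analysis was possible because the table holds 1 comparison with no values per sample, and for the same reason leaving out a replicate, a second count tool and an estimated correlation were not run. The 239 changed genes became 109 at an adjusted p of 0.01, 395 at 0.1, 90 with a log2 fold change of at least 1, 49 with Holm adjustment, 484 centred on ribosomal protein genes and 0 with a t distribution with 2 degrees of freedom. The first 4 differ by construction, being stricter or looser, and centring on ribosomal protein genes moved every gene by their median of 0.11. The t distribution, with which the threshold was out of reach, ignores the sharing of dispersion between genes and left 68 genes at an unadjusted p under 0.05, against 1634 with the normal distribution of the authors' table. The share of higher genes stayed below an equal share wherever genes were called, from 2.04% (Holm) to 36.6% (centred on means of at least 500), and was 7.44% centred on ribosomal protein genes and 30.6% after the trend was removed (170 genes, of which 154 were among the 239). Centring on means of at least 50, which moved every gene by only 0.0035, gave 23.8%. Nr1h2 stayed between -2.44 and -2.33 on the log2 scale. The median of all genes was -0.0035 for means of at least 50 and -0.0381 for means of at least 500, so abundant genes lay slightly lower; the cause was not tested. Of 11 lists past the threshold, 3 remained at a correlation of 0.05 (2-cell, sex-linked and nuclear receptor partners); 5 lists passed on log2 fold changes, 3 of them among the 11, and 6 on ranks; the cause was not tested. The 2-cell list passed in all 9 settings. Fisher's test passed 4 lists, and 2 with genes called at 0.01 and 2 at 0.1 (in both cases the 2-cell and stress lists); the cause was not tested. Of 46 named called genes, 44 stayed called after centring on means of at least 50 or of at least 500, 42 centred on ribosomal protein genes, 35 after the trend was removed and 17 with Holm adjustment. Abundance limits what could be called: a gene with a mean of 8 to 50 and the median standard error of that range needed a change of 4.02 times, so smaller changes of genes less precise than that were not called.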

Other observations

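A screen of 423 groups of genes that share a symbol root, chosen after the main results were seen, singled out 2. The Snhg genes, spliced hosts of small nucleolar RNAs, lay higher as a group (cameraPR on the 16 genes at a preset correlation of 0.01, p = 1.03e-05, adjusted p = 0.00436 over the 423 groups). Snhg20 (0.86 ± 0.20, SE) and Snhg5 (0.50 ± 0.13) were called in the authors' deposited table, while Snhg4 (0.57 ± 0.20) and Snhg11 (0.47 ± 0.16) were not. The 5 Dppa genes lay lower (adjusted p = 0.00441), mostly through Dppa1 (-1.12 ± 0.16), with Dppa2 at -0.37 ± 0.13 and Dppa3, the most abundant transcript in the authors' deposited table, at -0.26 ± 0.11. Outside the naming rule, and picked after their values were seen, are 3 more called genes. Beside H2-Eb1, the class II chain H2-Ab1 was higher in the authors' deposited table (1.02 ± 0.25, adjusted p = 0.00551), and the endoplasmic reticulum factor Manf rose there together with Pdia6 (0.46 ± 0.12, adjusted p = 0.0149). The desaturase paralogue Scd3 was lower like Scd1 (-0.74 ± 0.18, adjusted p = 0.00557, authors' deposited table).

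X-linked genes were over-represented among the lower ones. Of 438 with an adjusted p, 19 were called lower and 1 higher (4.34% lower, against 1.41% of 11553 autosomal genes; Fisher's exact test, two-sided, p = 3.71e-05). Genes of 1 chromosome are not independent, so this p describes the imbalance. Those with a mean of at least 50 had a median log2 fold change of -0.13, against 0.00034 for autosomal genes. X was the 1 chromosome of 21 past an adjusted p of 0.05 (adjusted p = 0.0266), and also at means of at least 50 (adjusted p = 0.00146 over the 20 chromosomes left). After the length and GC trend was removed its adjusted p was 0.286, and Y was then the 1 chromosome past 0.05, upward (adjusted p = 0.0326, against 0.123 before).

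In the patterns below, the tests of shared reads, of developmental stage and of library scaling were chosen after the result was seen. List tests are cameraPR at a preset correlation of 0.01.

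The 2-cell list was shifted downward in siNr1h2, with 7 of 23 members called lower, 0 called higher and 7 above 0. The shift of the authors' statistics remained after the length and GC trend was removed (p = 1.26e-11), which argues against that trend as the whole cause. Reads shared between copies stay open, because 1 gene per family (p = 2.35e-13 over the authors' statistics) still shares reads with its copies, while of the 6 members outside multi-copy families 3 lay below 0 and 3 above, and the shift of the authors' statistics over these 6 (p = 0.0145) rested on Zfp352 (p = 0.719 without it). A later stage of the siNr1h2 embryos, which would bring fewer 2-cell but more trophectoderm transcripts, stays open too: the trophectoderm list was shifted downward, not upward, at an adjusted p of 0.0110, but this rose to 0.125 at a correlation of 0.05, 0.0697 on ranks and 0.255 on log2 fold changes. That Nr1h2 helps to sustain these transcripts is a hypothesis found on the same data and not tested for direct action, and unintended silencing by the siRNA pool, weighed for the next pattern, stays open here too.

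More genes were lower than higher. Scaling of the libraries stays open as a cause. Centring on genes with means of at least 500 (median -0.0381) took the split from 184 lower and 55 higher genes to 142 and 82. This left 1.73 lower genes per higher one, against a limit of 1.5 set after the result was seen. Centring on ribosomal protein genes (median 0.11) moved the split the other way, which the sign of that median fixes in advance, so it decides nothing. An upward shift of all log2 fold changes by 0.05 would bring lower genes to at most 1.5 times the higher ones. A shift by 0.075 would split the calls evenly (120 higher, 116 lower), and the table holds no external standard. After removal of the length and GC trend the imbalance held (exact binomial test, p = 4.49e-07), although the number of lower genes fell from 184 to 118, so such a trend may account for some of the calls. Unintended silencing by siRNA seeds stays open. No heptamer of 15876 in 3′ untranslated regions was tied to lower Wald statistics (linear regression over 8646 genes; smallest adjusted p = 0.228 among those of the Nr1h2 mRNA), but this missed threshold is not evidence of absence, since the 95% interval for that heptamer's shift in the statistic reaches -0.31 and for rarer ones -0.85. The 7 heptamers with the lowest statistics all occur in the Nr1h2 mRNA on one strand or the other, against 24.8% of all heptamers. The heptamer next in rank does not occur there, so the cut at 7 lies where the run ends. Of the 7, 2 lie in the sense strand that guide seeds would match, against 13.9% of all heptamers. These counts were made after the scan was seen and decide nothing.

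Y-linked genes lay above 0 when pooled, by 0.34 ± 0.10 (SE) on the log2 scale over 8 genes, 6 of them above 0 and 1 called (Kdm5d), with uneven sizes (Cochran's Q from the authors' standard errors, p = 0.0474), but as a chromosome they missed the threshold (cameraPR, p = 0.0117, adjusted p = 0.123). A larger share of male embryos among the siNr1h2 morulae is a candidate explanation, and it needs X-linked genes to be lower, which they were (p = 0.00127 at the preset correlation). Xist would also fall with fewer female embryos, but it lay above 0, within its error (0.12 ± 0.14 in the authors' deposited table), so the values do not all point the same way. Its value is uncertain, because reads of Tsix are not separated from it. A response of X- and Y-linked genes to the knockdown stays open and untested, since the sex of the embryos is not given in the sources used here.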
